A study of Mus musculus with 2 samples.

How the data were processed

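Small RNA was profiled in the retina of wild-type CD-1 mice (an outbred laboratory strain) on the day of birth, postnatal day 0. The series held 1 group with 2 libraries, numbered replicate 1 and replicate 2 in the labels. Per the labels' protocols, total RNA was extracted with TRIzol and small RNA of 18 to 30 nt was taken from a denaturing gel. Libraries were made from the gel-purified RNA of 1 µg total RNA with a ligation-based kit for small RNA, and cDNA of 60 to 80 nt was taken from a second gel before amplification. Both gel steps favour RNA in the size range of mature miRNAs, so longer precursors were largely left out of the measurement. The adapter ligation differs in yield between RNA sequences, so a level compared between different miRNAs in a library holds the ligation yield as well as the amount of RNA. The labels do not state whether the replicates came from separate animals or litters, so the spread between them may be technical.

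Per the submitters' processing notes, reads were written out with bcl2fastq 2.17.1.14. The aligner, the counting program and the genome build are not given in the sources used here, and neither are adapter trimming and mismatch settings. The deposited count table held estimated counts, with 1 value per mature miRNA and library and no scaling. Of the cells, 6.77% in replicate 1 and 5.96% in replicate 2 were not whole numbers, and miRNAs with the same mature sequence held equal shares, so reads that fitted several miRNAs appeared to have been split between them. These fractional values sat in miRNAs holding 24.4% and 29.1% of the counts, and counts were rounded to whole numbers for every test. The deposited CPM table held counts scaled to a common size by a library total chosen by the authors. Its columns summed to 88.5% of the value for a whole library in both libraries, so the rows analysed here are part of the authors' total. CPM recomputed from the counts with the totals that these values imply lay within 0.1 of the deposited CPM for 1358 and 1357 of the 1358 miRNAs. The third deposited table held text, namely the most frequent read sequence of each miRNA in each library, marked against miRBase release 21 per the file headers. The header explains the marks for mismatches and for added bases at either end. The mark for missing 5′ bases was read from the values, and a shorter 3′ end carried no mark. No column of other samples was present.

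CPM was computed here as the count over the total of the count table, 8337902 in replicate 1 and 8118208 in replicate 2. It was 1.13 times the deposited CPM in both libraries, and this factor cancels in every ratio within a library. A count of 0 allowed a level of up to 0.36 CPM in replicate 1 and 0.37 CPM in replicate 2 (3 counts of the total). A count of 10 carried a counting error of 31.6%. Exact binomial 95% intervals and these limits cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

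Levels are the mean and SD of CPM over the 2 libraries, with no test. The share of counts was computed for 22 lists of miRNAs, 12 of them markers of cells or tissues other than the neural retina. The median of each list's detected members was placed among 10000 random lists of the same size drawn from all detected miRNAs. Within a library, 2 miRNAs or lists were compared by the log2 ratio of their counts, with 0.5 added to each count, and an exact two-sided binomial test of equal counts with Benjamini-Hochberg adjustment. A difference was called where both libraries had the same sign and an adjusted p below 0.05 and the mean log2 ratio was over 2 SD. The binomial test covers counting error only, and an SD from 2 libraries is imprecise. A called difference near 2 SD is therefore weak evidence of a difference beyond these libraries. Arms were compared in the same way for hairpin names with both arms listed and at least 10 counts over both arms in each library. A hairpin with a 4-fold or larger ratio in both libraries was counted as dominated by that arm. Libraries were compared by an exact two-sided binomial test of the counts of each miRNA with at least 10 counts over both libraries, with the expected share from the table totals and Benjamini-Hochberg adjustment at 0.05. This test compares libraries, not conditions. The spread beyond counting error was estimated with edgeR 4.0.16 (estimateDisp with an intercept and TMM scaling) in R 4.3.3. Other values were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.

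The lists, tests, thresholds and the rule for named miRNAs were fixed before the data were examined. The rule took the 20 miRNAs with the highest mean CPM, every detected member of the list of miR-216 and miR-217 and up to 4 members with the highest level in every other list. It also took the 5 miRNAs higher and the 5 lower in replicate 2 with the largest difference at 10 CPM or more, the 5 hairpins with the most even arms and the 5 highest 3p-dominant hairpins at 100 CPM or more. It named 110 miRNAs. The pairs of miRNAs and lists set against each other were chosen after counts had been seen, as were other miRNAs named outside the rule.

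Positions came from an exact match of the most frequent sequences to the hairpin transcripts of GENCODE M21 (build GRCm38), which need not be the authors' build. Of 1212 miRNAs with a sequence, 894 were placed in a hairpin of the same name, and they held 96.8% of the counts. The scripts were tested on simulated data with known answers. Of simulated differences between the libraries, 79 of 100 miRNAs changed 2-fold were recovered, and 36 of 100 with a smaller change, below 1.5-fold. Among the 713 miRNAs run, 0 of 513 unchanged miRNAs were called. These counts were drawn with counting error only and known library sizes. They therefore cannot show calls that come from spread beyond counting error or from scaling. A simulated coefficient of variation of 0.1 was estimated at 0.103, and 300 of 312 hairpins were put in the right arm class. The simulated arm ratios lay away from the 4-fold limit and held counting error only. They therefore do not show how reliably hairpins near that limit are classed. Alternatives were other count minimums, TMM and DESeq2 1.42.0 size factors as scaling, the edgeR exact test without dispersion, the deposited CPM, levels without the most abundant miRNA, 1 arm per hairpin, a 2-fold arm threshold and each library left out.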

Results

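The series measured mature miRNAs in the newborn wild-type mouse retina, and its title places the profile in a study of miR-216b, the transcription factor Foxn3 and the generation of amacrine cells, the inhibitory interneurons of the inner retina. The 2 libraries of the single group held 8337902 and 8118208 counts over 1358 miRNAs. Of these, 924 were detected in both libraries, 1151 in at least 1 library and 207 in neither. A mean level of at least 10 CPM was reached by 365 miRNAs, at least 100 CPM by 180, at least 1000 CPM by 74 and at least 10000 CPM by 15. With 1 group the design holds no condition to compare, so the questions it answers are which miRNAs the newborn retina held, at what level, in which form, and how closely the 2 libraries matched.

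A few miRNAs held most of the counts in the newborn retina, with miRNAs of neural and sensory tissue among the highest. miR-9-5p, a miRNA of neural progenitors and neurons, held 22.7% ± 0.169 of the counts (SD, n = 2). It was followed by miR-182-5p of the sensory-organ cluster at 110064 ± 10501 CPM, let-7i-5p of the developmental timing family at 99231 ± 4210 CPM, miR-26a-5p at 87684 ± 13293 CPM and miR-183-5p at 65116 ± 3926 CPM. The 10 highest miRNAs of each library held 70.5% ± 0.696 of its counts, the 50 highest held 92.3% ± 0.223, and 40 ± 1.41 miRNAs made up 90% of the counts. The rest of the 10 highest were let-7f-5p (29520 ± 959 CPM), miR-30d-5p (28808 ± 345 CPM), miR-148a-3p (21571 ± 1929 CPM), let-7a-5p (18061 ± 799 CPM) and miR-181a-5p (17710 ± 2269 CPM). Ranks 11 to 20 were held by miR-25-3p, miR-99b-5p, let-7g-5p, miR-92a-3p, miR-7a-5p, miR-181b-5p, miR-30c-5p, let-7c-5p, miR-128-3p and miR-99a-5p, from 16363 ± 552 CPM for miR-25-3p down to 8015 ± 578 CPM for miR-99a-5p. miR-9-5p exceeded miR-182-5p by 2.07-fold (log2 ratio 1.05 ± 0.13, SD, n = 2), with the same sign in both libraries in the exact binomial test. miR-9-5p has 3 hairpins with the same mature sequence, TCTTTGGTTATCTAGCTGTATG, on chromosome 3 (Mir9-1, 88215598 to 88215686, in an intron of the lincRNA Gm3764), chromosome 13 (Mir9-2, 83738814 to 83738885, in an exon of the lincRNA C130071C03Rik) and chromosome 7 (Mir9-3, 79505264 to 79505353, in an intron of the lincRNA Mir9-3hg), and its count cannot be assigned to any of them. let-7i-5p comes from a single hairpin on the minus strand of chromosome 10 (122985640 to 122985724, in an exon of the transcribed pseudogene D630033A02Rik). miR-26a-5p comes from Mir26a-1 on chromosome 9 (119031796 to 119031885, in an intron of Ctdspl) and Mir26a-2 on chromosome 10 (126995530 to 126995613, in an exon of Ctdsp2).

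**Figure D1:**
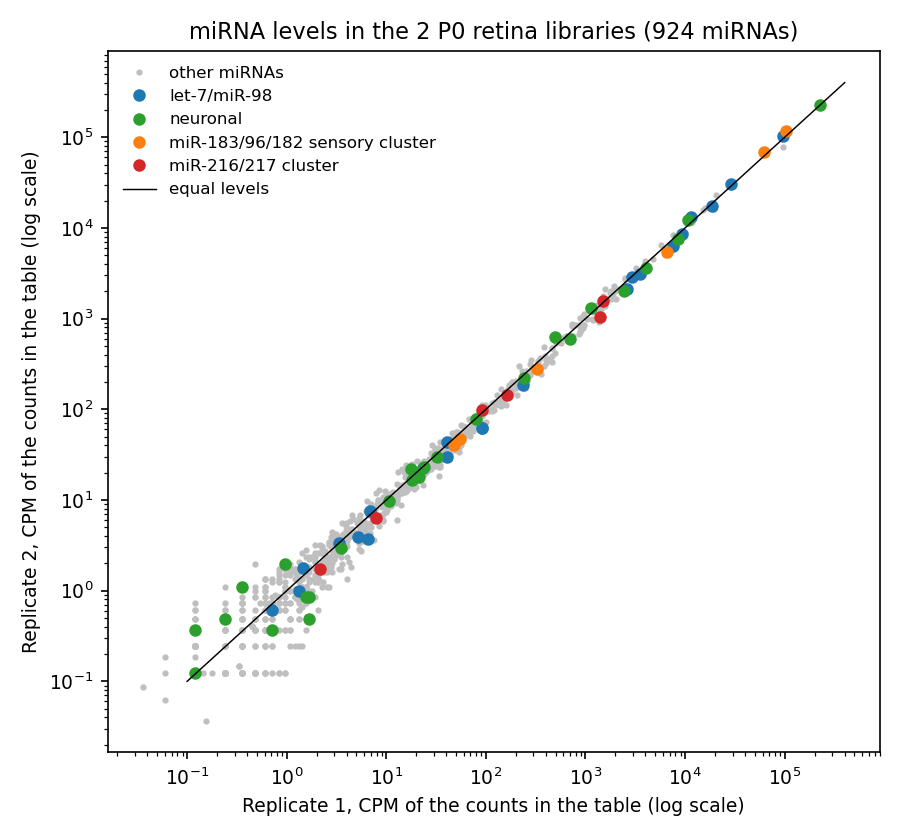
Level of each of the 924 miRNAs detected in both libraries, in CPM of the table total, with replicate 1 on the x axis and replicate 2 on the y axis, both on a log scale. Colours mark 4 lists and the line marks equal levels; miR-9-5p is the highest point, and the points spread out below about 10 CPM.

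The cluster of miR-216 and miR-217, which holds the miRNA named in the title of the series, was among the more abundant of the detected miRNAs but far below the leading ones. miR-216b-5p reached 1216 ± 249 CPM (SD, n = 2) and rank 65 of 1358, close to its cluster neighbour miR-217-5p at 1538 ± 31.9 CPM and rank 59. miR-216a-5p was lower, at 153 ± 15.4 CPM and rank 158. Within the libraries, miR-216b-5p exceeded miR-216a-5p by 7.88-fold (log2 ratio 2.98 ± 0.15) and miR-217-5p exceeded miR-216a-5p by 10.1-fold (log2 ratio 3.33 ± 0.18), and both differences were called. The log2 ratio of miR-217-5p over miR-216b-5p was 0.12 in replicate 1 and 0.59 in replicate 2, a mean of 0.35 ± 0.33, and was not called because it lay within 2 SD.

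The other arms of the cluster were lower. miR-216a-3p was at 94.8 ± 4.28 CPM, miR-216b-3p at 7.16 ± 1.07 CPM and miR-217-3p at 1.94 ± 0.307 CPM. All 6 members were detected in both libraries and together held 0.301% ± 0.023 of the counts, with the median member at percentile 97.4 of random lists of the same size. The other lists not marked as outside the neural retina lay from 96.4 (neuronal) to 99.98 (miR-26/29/30), so a high percentile was not particular to this cluster. miR-216c was also in the list but had no entry among the 1358 miRNAs. miR-216b-5p was 1392 CPM in replicate 1 (exact 95% interval 1367 to 1418) and 1040 CPM in replicate 2 (1018 to 1062), a log2 ratio of -0.42 (adjusted p = 4.66e-92, exact binomial test between the libraries). The log2 ratio of miR-217-5p between the libraries was 0.042 (adjusted p = 0.0661, exact binomial test). Scaled by TMM, these ratios were -0.30 and 0.16 and both passed the test, so the direction of miR-216b-5p did not depend on the scaling.

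On GRCm38 the 3 hairpins lie on the plus strand of chromosome 11. Mir216b spans 28746191 to 28746276, outside any annotated transcript of its strand other than its own, and the most frequent miR-216b-5p read AAATCTCTGCAGGCAAATGTG covers 28746204 to 28746224. Mir216a spans 28757012 to 28757083 and Mir217 spans 28763728 to 28763835, both in introns of the lincRNA Gm12082. The most frequent miR-217-5p read TACTGCATCAGGAACTGACTGG covers 28763761 to 28763782. The most frequent miR-216a-5p read was TAATCTCAGCTGGCAACTGTG in 1 library and a base longer, TAATCTCAGCTGGCAACTGTGA, in the other.

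**Figure D2:**
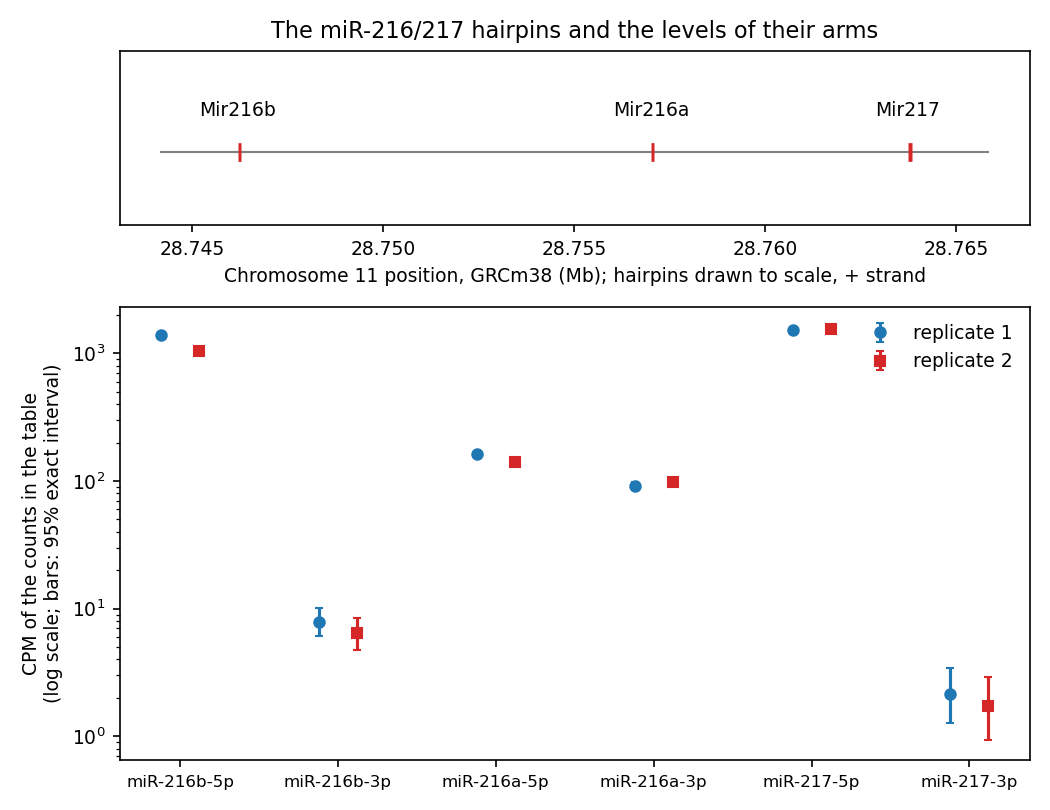
Top, positions of the Mir216b, Mir216a and Mir217 hairpins on chromosome 11 of GRCm38, in Mb and to scale. Bottom, level of each arm in CPM on a log scale for replicate 1 (circles) and replicate 2 (squares), with exact binomial 95% intervals that are smaller than the symbols above 90 CPM; miR-216b-5p and miR-217-5p lie above 1000 CPM in both libraries, and the 3p arms of the same hairpins lie below 10 CPM.

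Neural, sensory and developmental timing miRNAs took most of the retina's counts when grouped by list. The neuronal list held 25.6% ± 0.174 of the counts (SD, n = 2), the let-7/miR-98 list 18.4% ± 0.327, the sensory list of miR-183, miR-96 and miR-182 18.2% ± 1.36 and the miR-26/29/30 list 14.3% ± 1.38. The neuronal share rested on miR-9-5p, since without that miRNA the other members held 3.68% of the remaining counts. The neuronal list exceeded the let-7/miR-98 list by 1.39-fold (log2 ratio 0.47 ± 0.016, called). The sensory list could not be ranked against let-7/miR-98, since the log2 ratio was -0.081 in replicate 1 and 0.036 in replicate 2.

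Levels within the neuronal list spanned the whole range. After miR-9-5p came miR-7a-5p at 11493 ± 1192 CPM, miR-128-3p at 8041 ± 640 CPM and miR-9-3p, from the other arm of the miR-9 hairpins, at 3817 ± 337 CPM. miR-124-3p, the most studied miRNA of mature neurons, was at 649 ± 73.9 CPM and rank 91. The counts of miR-9-5p exceeded those of miR-124-3p by 351-fold (log2 ratio 8.46 ± 0.18, called), and the ligation yield of both sequences is part of this ratio. miR-218-5p stood at 2246 ± 297 CPM and miR-129-5p at 1219 ± 131 CPM, whereas miR-138-5p (23.3 ± 0.591 CPM), miR-132-3p (17.4 ± 0.96 CPM) and miR-137-3p (1.09 ± 0.839 CPM) were low. Of the 28 arms in the list 26 were detected in both libraries, and 16 reached 10 CPM. The median member lay at percentile 96.4 of random lists.

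The cluster of miR-183, miR-96 and miR-182, known from photoreceptors and the hair cells of the ear, was uneven. miR-182-5p exceeded miR-183-5p by 1.69-fold (log2 ratio 0.76 ± 0.051) and miR-96-5p by 18.5-fold (4.21 ± 0.33), and miR-183-5p exceeded miR-96-5p by a log2 ratio of 3.45 ± 0.28, all called. miR-96-5p was at 5964 ± 799 CPM and miR-182-3p at 302 ± 33.7 CPM. On GRCm38 the hairpins lie on the minus strand of chromosome 6, Mir182 at 30165918 to 30165992, Mir96 at 30169446 to 30169551 and Mir183 at 30169668 to 30169737, outside other annotated transcripts of that strand. The cluster exceeded the lists of all cells outside the neural retina together by 29.2-fold (log2 ratio 4.87 ± 0.26, called).

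In the let-7/miR-98 list, 9 of 23 arms were above 1000 CPM, led by let-7i-5p, let-7f-5p, let-7a-5p and let-7g-5p (12358 ± 1131 CPM). The list exceeded the proliferation-linked miR-17~92 list and its paralogs by 4.79-fold (log2 ratio 2.26 ± 0.014, called). The miR-17~92 list held 3.84% ± 0.0323 of the counts, led by miR-25-3p, miR-92a-3p (11769 ± 106 CPM), miR-93-5p (4003 ± 53.3 CPM) and miR-20a-5p (2143 ± 58.1 CPM). Family members differ by few bases, so reads could be exchanged between them in counting. In the miR-26/29/30 list, miR-26a-5p, miR-30d-5p, miR-30c-5p (9290 ± 824 CPM) and miR-30a-5p (6079 ± 559 CPM) were high, while the highest miR-29 arm, miR-29a-3p, was at 11.2 ± 0.992 CPM.

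The remaining retinal lists were smaller. The miR-181 list held 3.29% ± 0.31 of the counts, with miR-181a-5p followed by miR-181b-5p (9309 ± 696 CPM), miR-181d-5p (4678 ± 166 CPM) and miR-181a-1-3p (812 ± 39.7 CPM). The list of the imprinted Dlk1-Dio3 region held 2.23% ± 0.186, and 85 of its 93 arms were detected in both libraries. Its highest members were miR-541-5p (3952 ± 239 CPM), miR-381-3p (2648 ± 212 CPM), miR-370-3p (2400 ± 212 CPM) and miR-434-5p (2156 ± 351 CPM). The miR-125 list held 0.742% ± 0.108, and miR-125a-5p (5660 ± 963 CPM) exceeded miR-125b-5p (1476 ± 118 CPM) by 3.81-fold (log2 ratio 1.93 ± 0.13, called). Its other named members were miR-125b-1-3p at 168 ± 0.155 CPM and miR-125a-3p at 77.6 ± 2.24 CPM. The list of miR-15, miR-16, miR-322 and their relatives held 0.16% ± 0.0128, with miR-16-5p at 865 ± 112 CPM, miR-16-1-3p at 192 ± 11.8 CPM, miR-322-3p at 125 ± 7.69 CPM and miR-15b-5p at 106 ± 9.99 CPM.

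**Figure D3:**
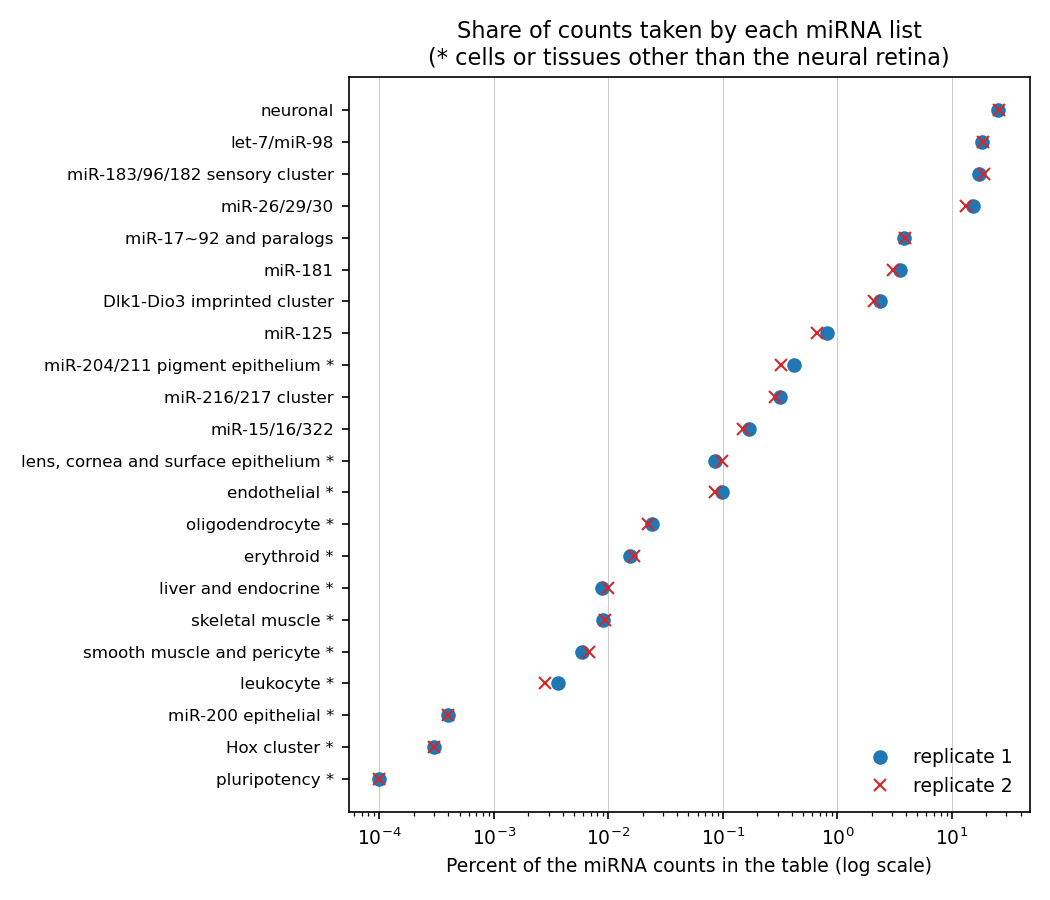
Percent of all counts taken by each of the 22 miRNA lists, on a log scale, in replicate 1 (circles) and replicate 2 (crosses). The neuronal, let-7/miR-98, sensory and miR-26/29/30 lists each hold more than 10%, and the lists marked with an asterisk, for cells or tissues other than the neural retina, hold less than 0.5% each.

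miRNAs listed as markers of cells and tissues other than the neural retina were detectable but low, at 0.622% ± 0.0633 of the counts for the 12 lists together. The largest of them was the pigment epithelium list (0.37% ± 0.0639), in which miR-204-5p was at 3389 ± 558 CPM and miR-204-3p at 300.5 ± 80.7 CPM. This list exceeded that of miR-216 and miR-217 in both libraries. The log2 ratio of the latter over the former was -0.39 in replicate 1 and -0.19 in replicate 2. Its mean of -0.29 ± 0.14 was called but lay only just over 2 SD, so the difference is weakly supported. miR-204 is not restricted to the pigment epithelium, since the lens and other eye tissues also express it. The counts do not show which cells held it, so neither this share nor the total of the 12 lists measures RNA from outside the neural retina. miR-211-5p was at 5.62 ± 0.453 CPM and its most frequent read carried the substitution A17G relative to that of miR-204-5p (positions counted from 1 at the 5′ end, miR-204-5p base first), so its count is uncertain. miR-211-3p was at 0.122 ± 0.0023 CPM.

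Vascular and surface epithelial miRNAs came next. The endothelial list held 920 ± 93.3 CPM, nearly all from miR-126a-3p (905 ± 90.9 CPM), with miR-126a-5p at 14.8 ± 2.3 CPM. The lens, cornea and surface epithelium list held 925 ± 91.7 CPM from miR-184-3p (804 ± 92.8 CPM) and miR-203-3p (121 ± 0.802 CPM), and miR-205-5p was at 0 in both libraries. The oligodendrocyte list held 0.023% ± 0.0013 of the counts, mainly miR-219a-1-3p (175 ± 3.39 CPM) and miR-338-5p (43.8 ± 13.9 CPM). The opposite arms were low, with miR-338-3p at 4.3 ± 1.38 CPM and miR-219a-5p at 3.83 ± 0.358 CPM. The erythroid list held 160.4 ± 10.4 CPM, mostly miR-486a-5p and miR-486b-5p, which share a mature sequence and split reads (62.3 ± 1.18 CPM each), and miR-486a-3p (34.5 ± 8.17 CPM), while miR-451a was at 0.365 ± 0.0069 CPM.

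The other lists outside the neural retina were each below 100 CPM. The liver and endocrine list held 93.8 ± 7.61 CPM, with miR-375-3p at 72.9 ± 7.39 CPM and miR-122-5p at 20.9 ± 0.223 CPM. The skeletal muscle list held 91.3 ± 2.75 CPM, with miR-206-3p at 70.7 ± 3.31 CPM and miR-1a-3p at 18.3 ± 5.5 CPM. The smooth muscle and pericyte list held 62.8 ± 5.23 CPM, almost wholly miR-143-3p (61.7 ± 4.6 CPM). The leukocyte list held 32.0 ± 5.41 CPM, led by miR-146a-5p (25.2 ± 4.51 CPM), and miR-223-3p and miR-150-5p were at 0 in both libraries. The miR-200 list held 3.59 ± 0.0183 CPM, the Hox list 2.68 ± 0.222 CPM and the pluripotency list 0.608 ± 0.0115 CPM, each from at most 30 counts in a library.

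Of the hairpins with both arms listed, 77.2% gave mostly reads of a single arm in both libraries. Of 312 hairpins, 126 were dominated 4-fold or more by the 5p arm, 115 by the 3p arm, and 71 were counted as using both. The 5 highest 3p-dominant hairpins were miR-148a (mean log2 ratio of 5p over 3p -8.62 ± 0.15), miR-25 (-8.00 ± 0.15), miR-151 (-7.39 ± 0.23), miR-320 and miR-381. miR-320-5p was at 0 in both libraries against 3052 ± 220.3 CPM for miR-320-3p, and miR-381-5p held 2 and 1 counts. In the 129 hairpins with at least 100 CPM over both arms, 63 were 5p-dominant, 46 were 3p-dominant and 20 used both. The 5 most even were miR-28a (54.6% of counts in the larger arm), miR-136 (53.6%), miR-30b (53.8%), miR-503 (56.9%) and miR-423 (58.1%). miR-28a and miR-136 favoured opposite arms in the 2 libraries and were not called, whereas miR-30b (log2 ratio 0.22 ± 0.014), miR-503 (0.40 ± 0.10) and miR-423 (-0.47 ± 0.14) had a called difference.

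**Figure D4:**
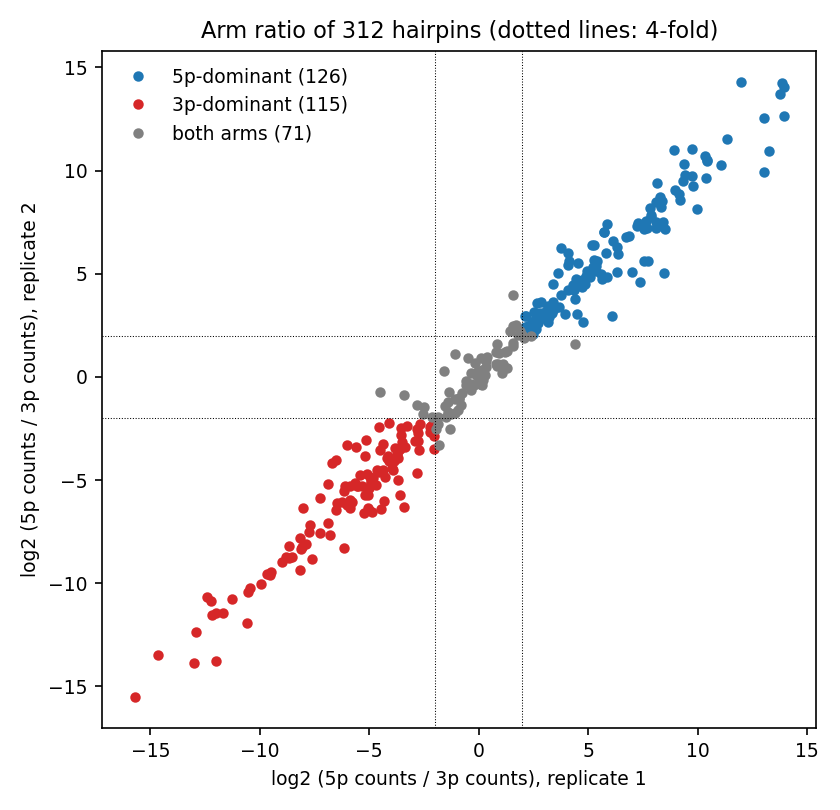
Log2 ratio of 5p over 3p counts (0.5 added to each) of 312 hairpins, replicate 1 on the x axis and replicate 2 on the y axis, with dotted lines at 4-fold. The 126 5p-dominant hairpins lie at the upper right, the 115 3p-dominant hairpins at the lower left, and 71 lie between.

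The most frequent reads of miRNAs with high counts mostly started at the annotated 5′ end, which sets the bases that pair with targets. Of the 180 miRNAs at 100 CPM or more, 175 had the same most frequent sequence in both libraries and 168 started at the miRBase base in both. In 11, holding 0.867% of the counts, the start was shifted in both libraries, by 1 base in 10 of them, 6 later and 4 earlier. The highest was miR-9-3p, whose most frequent read TAAAGCTAGATAACCGAAAGTA started 1 base later than the miRBase entry, followed by miR-101a-3p (1830 ± 383 CPM, read GTACAGTACTGTGATAACTGA, 1 base earlier), miR-140-3p (1043 ± 99.1 CPM, 1 base later) and miR-361-3p (842 ± 11.9 CPM, 1 base later). Added 3′ bases were found in 31 (17.2%). The last base was the only mismatch to miRBase in miR-19a-3p, miR-19b-3p and miR-345-3p. Below 100 CPM, 439 of 744 detected miRNAs had the same most frequent sequence in both libraries. miRNAs singled out here were chosen after their values were seen.

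The libraries ranked miRNAs alike but differed by more than counting error for many of them. Across miRNAs with at least 10 CPM, which are not independent replicates, Pearson's r of log2 CPM between the libraries was 0.997. Of 710 miRNAs tested, 198 (27.9%) differed in the exact binomial test, 59 higher and 139 lower in replicate 2. Scaled by TMM, 106 were higher and 81 lower, and with DESeq2 size factors 108 and 77, because the median log2 ratio of all tested miRNAs was -0.12 by table totals, -0.006 by TMM and 0.003 by DESeq2. Of the 198 called by table totals, 19 differed by 1.5-fold or more and 7 by 2-fold or more. The share called depended on the level, since 141 of the 180 miRNAs at 100 CPM or more were called by table totals. Low counts leave the test little power, so a miRNA that was not called need not be equal in the libraries. The coefficient of variation beyond counting error was 0.104 in edgeR and 0.204 as the median of DESeq2 dispersions. All 20 leading miRNAs were among the called by table totals, with a largest absolute log2 ratio of 0.31. Under TMM and DESeq2 scaling, 3 of them (miR-30d-5p, let-7a-5p and miR-92a-3p) were called in the opposite direction, and let-7c-5p was not called with DESeq2 size factors.

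The called miRNAs that differed by 2-fold or more were all below 10 CPM and are not named here. Among called miRNAs at 10 CPM or more, those lower in replicate 2 with the largest difference were miR-485-3p (log2 ratio -0.87), miR-574-5p (-0.67), miR-338-5p (-0.66), miR-669l-5p (-0.65, not called under TMM or DESeq2 scaling) and miR-543-3p (-0.59). Those higher at 10 CPM or more were miR-101c (0.63), miR-1a-3p (0.62), miR-20b-5p (0.61), miR-1298-5p (0.60) and miR-34b-3p (0.59), called under all 3 scalings. Only miR-543-3p among these was above 100 CPM, at 1149 ± 329 CPM. The Dlk1-Dio3 list had 26 of 75 tested members lower and 3 higher in replicate 2 (32 called adjusted over the list alone), and 19 lower and 4 higher by TMM (24 adjusted over the list alone). In the pigment epithelium list, miR-204-5p (-0.34) and miR-204-3p (-0.55) were lower in replicate 2 by all 3 scalings, 2 of 3 tested members and the same number adjusted over the list alone. In the let-7/miR-98 list 10 of 22 were lower and 3 higher (13 adjusted over the list alone), against 8 lower and 5 higher by TMM (14). In the miR-17~92 list 7 of 22 were lower and 3 higher (11 adjusted over the list alone), and this balance turned to 1 lower and 6 higher by TMM (8). In the sensory list, miR-182-5p (0.20) and miR-183-5p (0.12) were higher and miR-96-5p (-0.27) and miR-182-3p (-0.23) lower in replicate 2 by all 3 scalings. Adjusted over this list alone, 6 were called by table totals and 4 under TMM or DESeq2 scaling.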

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

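All alternatives were planned. A called pair passes in either library alone by the construction of the call, so leaving out a library tests nothing for the 12 called pairs. The 20 highest miRNAs shared 19 or 20 members with those of each other setting. Under TMM scaling 106 miRNAs were higher and 81 lower in replicate 2, and with DESeq2 size factors 108 and 77, since both raise replicate 2 relative to the table totals. Of the 198 calls by table totals, 140 and 136 kept their call and direction under these scalings, and 7 and 8 were called in the opposite direction. The coefficient of variation beyond counting error was 0.204 as the median of DESeq2 dispersions against 0.104 in edgeR, and the cause was not tested. Leaving miR-9-5p out of the total raised shares by construction, to 1573 CPM for miR-216b-5p, 0.39% for the list of miR-216 and miR-217, 23.5% for the sensory list, 23.8% for let-7/miR-98 and 0.804% for the lists outside the neural retina, and left 3.68% for the neuronal list. With only the larger arm of each hairpin, 5 list shares moved by more than their SD, to 25.2% for the neuronal list, 3.79% for miR-17~92, 0.145% for the list of miR-15, miR-16 and miR-322, 0.0125% for the erythroid list and, at 5 or fewer counts, the pluripotency list, and the other 18 did not. With either library left out, the log2 ratio of miR-217-5p over miR-216b-5p was 0.12 to 0.59 and that of the sensory over the let-7/miR-98 list -0.081 to 0.036, each past the counting test of the single library left, which has no replicate SD. A minimum of 100 counts over both arms left 196 hairpins, 70 of them 3p-dominant and 36 using both arms, and a 2-fold threshold put 41 in the latter class, both by construction. miR-216b-5p kept rank 62 to 70 over all settings. Depth limits statements on miRNAs near a count of 10, where the counting error is 31.6%. No paired analysis was possible because the series has a single group.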

Other observations

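Several abundant miRNAs belonged to none of the lists. Of the 50 highest miRNAs 12 were in no list, and they held 7.65% of the counts. After miR-148a-3p, the highest were miR-99b-5p (15446 ± 317 CPM, SD, n = 2), miR-99a-5p (8015 ± 578 CPM) and miR-21a-5p (8005 ± 633 CPM), a miRNA found in most tissues. Lower in this group were miR-151-3p (4135 ± 259 CPM), miR-872-5p (3494 ± 107 CPM), miR-191-5p (3328 ± 309 CPM), miR-340-5p (2985 ± 0.93 CPM), miR-103-3p (2598 ± 157 CPM), miR-744-5p (1995 ± 48.9 CPM) and miR-27b-3p (1914 ± 150.3 CPM).

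Hairpins next to each other in the genome were read at unequal levels. Among 65 pairs of neighbouring hairpins within 10 kb on the same strand, in 24 clusters, the larger arms differed by a median of 5.12-fold, and 24 pairs differed by 10-fold or more. Of the 597 hairpins located, 32 whose larger arm is shared by several loci were left out. In 59 of the 65 pairs the mean log2 ratio was over 2 SD between the libraries, whose median was 0.14. The sequences differ between neighbours, so ligation yield is part of these ratios.

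In what follows, the tests on arms, on cluster neighbours, on start positions and on mismatched reads were chosen after results of the same kind had been seen. The single group gives no biological contrast, so no biological explanation from the design was tested.

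The first pattern was the 198 miRNAs that differed between the libraries by more than counting error. Read length, GC content and scaling do not account for all of it. Of the 198 miRNAs, 145 were still called with the same sign after a trend on read length was removed (6 more reversed). After a trend on GC content 148 were (6 reversed), under TMM scaling 140 (7 reversed) and with DESeq2 size factors 136 (8 reversed). Removing a trend also removes the overall shift between the libraries, and the GC trend was negative throughout (-0.182 to -0.054). The log2 ratio hardly followed read length (Spearman rho 0.107) or GC content (0.075). Calls lost to these trends therefore cannot be told apart from calls lost to scaling, and whether either accounts for a part stays open. RNA from cells outside the neural retina stays open, since the 17 miRNAs of the 12 lists for other cells and tissues at 10 CPM or more had a median absolute log2 ratio of 0.207, between the median (0.18) and the upper quartile (0.284) of other miRNAs. The log2 ratios between libraries of the larger arms of neighbouring hairpins correlated across 65 pairs (Pearson r = 0.344, Spearman rho = 0.335). The permutation p was 0.0052, and 0.01 adjusted over 2 correlations. It treats the pairs as exchangeable, although consecutive pairs share a miRNA and all come from 24 clusters, so it may overstate the evidence. The bootstrap interval, from resampled whole clusters, was 0.091 to 0.532. Pearson r was 0.346 in the 62 pairs with different bases 2 to 8 and 0.389 in the 30 pairs outside chromosome 12. Neither subset excludes reads split between similar neighbouring miRNAs, which could also make their ratios alike. Different amounts of cluster transcripts in the RNA samples stay possible as a part of the cause. The arms of 80 hairpins had r = 0.227 (permutation p = 0.042, adjusted 0.042, bootstrap interval 0.02 to 0.41), below the 0.3 set for both tests, and the difference between the 2 correlations was not tested, so whether whole hairpins differed in amount cannot be told apart from differences in processing or ligation.

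The second pattern was that 54 miRNAs in replicate 1 and 46 in replicate 2 had a most frequent sequence listed but a count of 0. In 100% of them that sequence started 2 or more bases from the miRBase 5′ end, against 6.2% of the miRNAs with a count. A candidate explanation is that reads were counted only when they started within 1 base of the annotated end. Fewer than 5% of counted miRNAs were to have such a start, and this bound was missed. The bound does not follow from the explanation, because the most frequent read of a counted miRNA may itself not be among the counted reads. The miss therefore does not weigh against the explanation, which stays open because the counting rule is not given.

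The third pattern was 29 miRNA entries with 10 or more counts in both libraries whose most frequent read carried a mismatch to miRBase. Reads of a more abundant miRNA with 1 changed base do not account for the set, since 4 of the 29 lay within 1 substitution of a miRNA with 100 times the count. For those 4 this source stays possible: let-7j (G8A) and miR-3970 (A7T) relative to let-7i-5p, miR-378b (A1G) relative to miR-378a-3p and miR-211-5p (A17G) relative to miR-204-5p, with positions counted from 1 at the 5′ end and the abundant miRNA's base first. let-7j held 0.0425% and 0.0427% of the let-7i-5p count in the 2 libraries, and miR-3970 held 0.048% and 0.0471%.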
